A study of Rattus norvegicus with 12 samples.

How the data were processed

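Expression was measured by RNA sequencing in 12 rat cornea libraries, 3 each of Control, Alkali-burned, SF/HA and SF/HA-HEP-PAM, grouped by their labels. Per the labels' protocols, RNA was primed with barcoded poly(dT) primers that carry unique molecular identifiers, and cDNA was pooled before amplification. The deposited table holds FPKM values, 1 column per library. Per the series text, the authors trimmed reads with fastp, counted them with HTSeq-count, computed FPKM and tested with DESeq2 at q below 0.05 and a fold above 2 or below 0.5; per the submitters' processing notes, bcl2fastq, fastp, STAR, featureCounts and DESeq2 were used on build mRatBN7.2. The 2 sources differ in the counting tool. Neither says whether duplicate molecules were collapsed.

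The table had 30452 genes, of which 7092 carried no symbol, and 108 lines naming no gene, which were left out. The length column equals the full genomic span of each gene, introns included, so FPKM of long genes is low for their reads. FPKM times length was a whole multiple of 1 step per library (largest deviation 9.66e-06), which gave back read counts of 486264 to 2117399 per library. Depth and the level that 0 reads allow follow from these counts. Intervals and floors cover counting error only.

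Tests were made in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1), with a trend in the variance and all 12 libraries in 1 model of 4 group means. Genes with at least 1 FPKM in at least 3 libraries were tested, 6112 in all. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within the comparison and a log2 difference above 1 or below -1. A moderated F-test over the 4 groups used the same data. Of 33 gene lists, 22 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry; 601 of 669 list genes were in the table. Lists were matched by symbol and counts are of gene IDs, so a symbol carried by 2 gene IDs counts as 2 genes. The groups, the 6 comparisons, the lists, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls among called genes with a symbol, at least 5 FPKM in the higher group and no overlap between libraries, which chance gives in 10% of genes. Up to 4 members per described list, its highest-expressed member and 12 genes fixed in advance completed the rule; not every gene it allows is named.

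A fit with voom on the recovered reads (8653 genes with at least 10 reads in 3 libraries, 25 lists), thinning to the smallest library, a read minimum, protein-coding genes only and leaving out 4 libraries that stood apart were added after the data were seen. The 4 were Control replicate 1, apart in Col1a1 and Krt12, and Alkali-burned replicate 1, SF/HA replicate 2 and SF/HA-HEP-PAM replicate 3. The last 3 were the highest of their groups in S100a8 and S100a9. Leaving them out lowers the spread of these genes by choice, so that fit cannot test them. In simulated data with 200 genes changed, 43 to 48 of 100 genes changed 3-fold and 65 to 72 of 100 changed 6-fold were called across the 6 comparisons, with 0 in the wrong direction and 6 to 16 unchanged genes called. Comparisons that share the burned libraries were set beside 100 simulations of patches without effect, made by shuffling residuals of the libraries. Shuffling was chosen after a first form, which draws residuals with replacement, had been seen to let 1 library fill a group; values of both forms are given. No library or group was left out of the comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.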

Results

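Gene expression was measured by RNA sequencing in 12 rat cornea libraries, 3 in each of 4 groups named Control, Alkali-burned, SF/HA and SF/HA-HEP-PAM. The series concerns a detachable patch made from silk that is worn on the eye surface to take up mediators of inflammation. The labels do not spell out SF, HA, HEP or PAM, and they do not say whether the corneas of both patch groups were burned. They also do not say whether the replicates are separate animals, so the p-values measure only the spread between these samples. Reads assigned to genes ranged from 486264 to 1015788 in Control, 1173159 to 1265298 in Alkali-burned, 499061 to 957696 in SF/HA and 1245606 to 2117399 in SF/HA-HEP-PAM libraries. At these depths 0 reads on a gene of 1 kb allows up to 1.42 FPKM in the deepest library and up to 6.17 FPKM in the shallowest, for counting error only.

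The groups separated along both leading principal components. The first, with 28.4% of the variance, placed the 3 SF/HA-HEP-PAM libraries between 35.2 and 47.3 and all others at or below 7.38. The second, with 16.7%, placed Control between 21.7 and 31.7 and Alkali-burned between -30.0 and -24.5. In limma's F-test 1629 of 6112 genes differed among the 4 groups at the adjusted threshold. Without SF/HA-HEP-PAM replicate 1 the count was 1046 and without SF/HA-HEP-PAM replicate 3 it was 984. SF/HA-HEP-PAM libraries had the lowest share of mitochondrial rRNA, 1.56% ± 0.262 (SD, n = 3), against 2.69% ± 0.179 in Alkali-burned, 3.44% ± 0.452 in SF/HA and 4.77% ± 1.005 in Control. Their share of reads on lncRNA genes was 0.942% ± 0.115, against 0.617% ± 0.0331 in Alkali-burned, 0.629% ± 0.00514 in SF/HA and 0.715% ± 0.196 in Control. Control replicate 1 stood apart from the other Control libraries in tissue markers. Col1a1, a stromal collagen, took 4.32% of its reads (95% Wilson interval 4.27 to 4.38) against 1.55% and 1.68% in the other 2 (intervals 1.52 to 1.57 and 1.66 to 1.71). Krt12, the keratin of corneal epithelium, took 1.22% (1.19 to 1.25) against 2.62% and 2.40% (2.59 to 2.65 and 2.37 to 2.43).

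**Figure D1:**
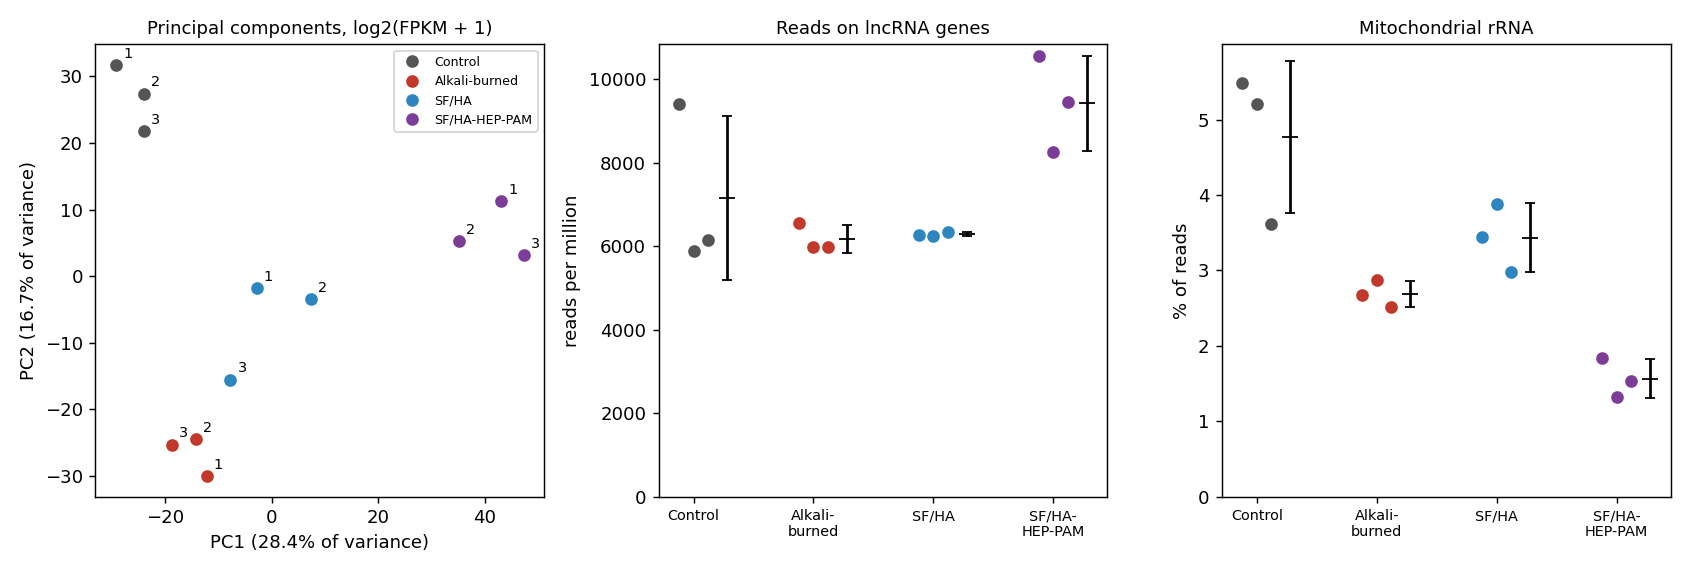
Left, position of the 12 libraries on the first and second principal component of log2(FPKM + 1), with 28.4% and 16.7% of the variance. Middle and right, reads on lncRNA genes (RPM) and mitochondrial rRNA as percent of reads, per library (dots; replicates 1 to 3 from left) with mean and SD (bars, n = 3); SF/HA-HEP-PAM libraries average 1.56% mitochondrial rRNA and Control libraries 4.77%.

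The comparison of Alkali-burned with Control corneas asks what the injury changed. Acta2, the actin of contractile wound cells, was 15.5 ± 5.58 FPKM after the burn and 1.04 ± 0.204 in Control (SD, n = 3; log2 difference 2.97, SE 0.50, adjusted p = 0.00677). Tagln, an actin-binding protein of the same cells, rose from 0.295 ± 0.0574 to 27.9 ± 10.99 FPKM (log2 4.42, SE 0.47, adjusted p = 0.000537). The Tagln value rests on 1 to 3 reads per Control library and its size depends on the pseudocount. Acta2 in Control (0.867 to 1.26 FPKM) also lay near the pseudocount of 1, so the size of its rises against Control depends on it. Among the largest rises were Crct1 (log2 4.32) and Cnfn (4.14), known from cornifying epithelium, the defensin Defb14 (3.98) and S100a7a (3.98, SE 0.24, adjusted p = 4.24e-05). The largest falls were Pla2g2a, a secreted phospholipase, from 1042 ± 635 to 37.9 ± 3.599 FPKM (log2 -4.54, SE 0.52, adjusted p = 0.000861), Angptl7 of the stroma (-4.42), the matrix protein Chad (-3.56) and the neuropeptide Npy (-2.40). In the submitters' build mRatBN7.2 Acta2 (ENSRNOG00000058039) lies on chromosome 1 from 231746548 to 231759554 and Pla2g2a (ENSRNOG00000016945) on chromosome 5 from 151076442 to 151079014.

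Of the gene lists fixed before the data were examined, macrophage markers gave the smallest camera p. Of 16 measured, 9 rose and 7 were not called (9 rose adjusted over the list alone; median log2 1.36, camera adjusted p = 1.07e-09, adjusted p = 0.0802 with an estimated correlation). Among them were the lysozyme Lyz2 (2.64), the complement subunit C1qa (2.36), the lysosomal Cd68 (1.43) and the secreted Spp1 (3.33). Of 9 complement genes 6 rose (6 adjusted over the list alone; camera adjusted p = 1.17e-06, adjusted p = 0.170 with an estimated correlation), with Cfd (3.18, and 2.56 without Control replicate 2), the inhibitor Serping1 (2.70) and C1s (2.27). In Control Spp1 (0.539 to 0.655 FPKM), Cfd (0 to 3.10) and C1qa (1.70 to 4.26) lay near the pseudocount of 1, so the size of their rises depends on it. Of 16 cytokines 5 rose (9 adjusted over the list alone; adjusted p = 0.00041, and 0.277 with an estimated correlation), with Il6 at 1.99 (SE 0.42, adjusted p = 0.0164) and Tnf at 1.79 (SE 0.38, adjusted p = 0.0160). Of 20 chemokines 5 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00228, and 0.277 with an estimated correlation). Cxcl1, which attracts neutrophils, rose from 412 ± 84.3 to 1593 ± 401 FPKM (1.94, SE 0.25, adjusted p = 0.00168), and Cxcl14 fell (-1.97). Of 15 matrix proteases and inhibitors 4 rose (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.00228, and 0.313 with an estimated correlation), with Mmp3 (2.95) and the inhibitor Timp1 (2.92). Of 21 corneal epithelium markers 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.81, adjusted p = 1.17e-06, and 0.277 with an estimated correlation); the metabolic enzyme Tkt fell (-1.28) and the secreted chaperone Clu rose (2.78).

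Smaller counts passed in the remaining called lists. Of 17 interferon genes 3 rose, Gbp2 among them at 2.37 (4 adjusted over the list alone; adjusted p = 8.96e-05, and 0.310 with an estimated correlation). Of 16 NF-kB and innate signalling genes 2 rose, the adhesion molecules Vcam1 (1.88) and Icam1 (1.67), with 2 adjusted over the list alone (adjusted p = 0.000927, and 0.277 with an estimated correlation). In Control Vcam1 (0.910 to 1.87 FPKM) and Icam1 (1.92 to 3.83) lay near the pseudocount of 1. The size of their rises against Control depends on it. Of 14 oxidative stress genes 4 rose, with the dismutase Sod2 (1.87) and the metallothionein Mt2A (1.68), again 4 adjusted over the list alone (adjusted p = 0.0287, and 0.310 with an estimated correlation). Of 7 MHC class II genes 1 rose, Cd74 (1.85; 1 adjusted over the list alone; adjusted p = 0.0110, and 0.313 with an estimated correlation). Of 14 cell cycle genes 1 rose (2 adjusted over the list alone; adjusted p = 0.00463, and 0.444 with an estimated correlation). Of 13 mitochondrially encoded genes 1 fell (1 adjusted over the list alone; adjusted p = 9.54e-05, and 0.277 with an estimated correlation), and of 38 ribosomal protein genes (35 symbols, 3 of them on 2 gene IDs) 0 were called by limma (1 rose adjusted over the list alone; median 0.31, adjusted p = 5.29e-05, and 0.475 with an estimated correlation). The other 9 lists tested did not pass. Stressed and cornifying epithelium had 5 of 11 genes (10 symbols) higher and 1 lower (camera adjusted p = 0.0511). Myofibroblast and matrix genes had 4 of 19 higher and 4 lower (adjusted p = 0.980), with Acta2 and Tagln higher and the collagen Col1a1 lower at -1.91 (SE 0.36, adjusted p = 0.0103). Keratocyte markers had 2 of 11 lower, Angptl7 and the proteoglycan Kera (-1.85, SE 0.38, adjusted p = 0.0140); their median was 0.45, their mean -0.22, and camera's direction was up (adjusted p = 0.980). The other 6 gave adjusted p = 0.0920 for the unfolded protein and heat shock response, 0.187 for hypoxia and glycolysis, 0.244 for conjunctival and goblet cell markers, 0.366 for immediate early genes, 0.799 for angiogenic factors and 0.930 for epithelial-mesenchymal transition regulators. Adm, a hypoxia-responsive vasodilator peptide, fell by 2.00.

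Across all genes 270 were higher and 78 lower after the burn in limma, 77.6% higher, against 63.3% higher after quantile normalization. Without Alkali-burned replicate 3 the count of 348 became 225. Of 34 called genes named here, 31 kept the call whichever library was left out. Il6 lost it without Control replicates 2 or 3 or Alkali-burned replicates 1 or 3 (adjusted p = 0.0573, 0.0530, 0.0610 and 0.0503), Tnf without Alkali-burned replicate 3 (0.0621), and Kera without Alkali-burned replicates 2 or 3 (0.0521 in both fits). Not called were Il1b (log2 1.43, SE 0.53, adjusted p = 0.132), Ccl2 (1.45, SE 0.41, 0.0560), S100a8 (2.44, SE 1.32, 0.296), Mmp9 (1.54, SE 0.65, 0.185) and Vegfa (0.77, SE 0.34, 0.207). Krt12 was not called either, at -0.88 (SE 0.31, adjusted p = 0.113), but passed without Control replicate 1 (-1.23, adjusted p = 0.0166). Il1b passed with library weights (adjusted p = 0.0160) and with only the compared libraries (0.0219), and Ccl2 at 5 FPKM or more (0.0358) and with library weights (0.0457). Of the settings added after the data were seen, Il1b passed without the 4 libraries that stood apart (0.0146), and Ccl2 with voom (0.0139), at least 10 reads (0.0302) and protein-coding genes only (0.0411).

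**Figure D2:**
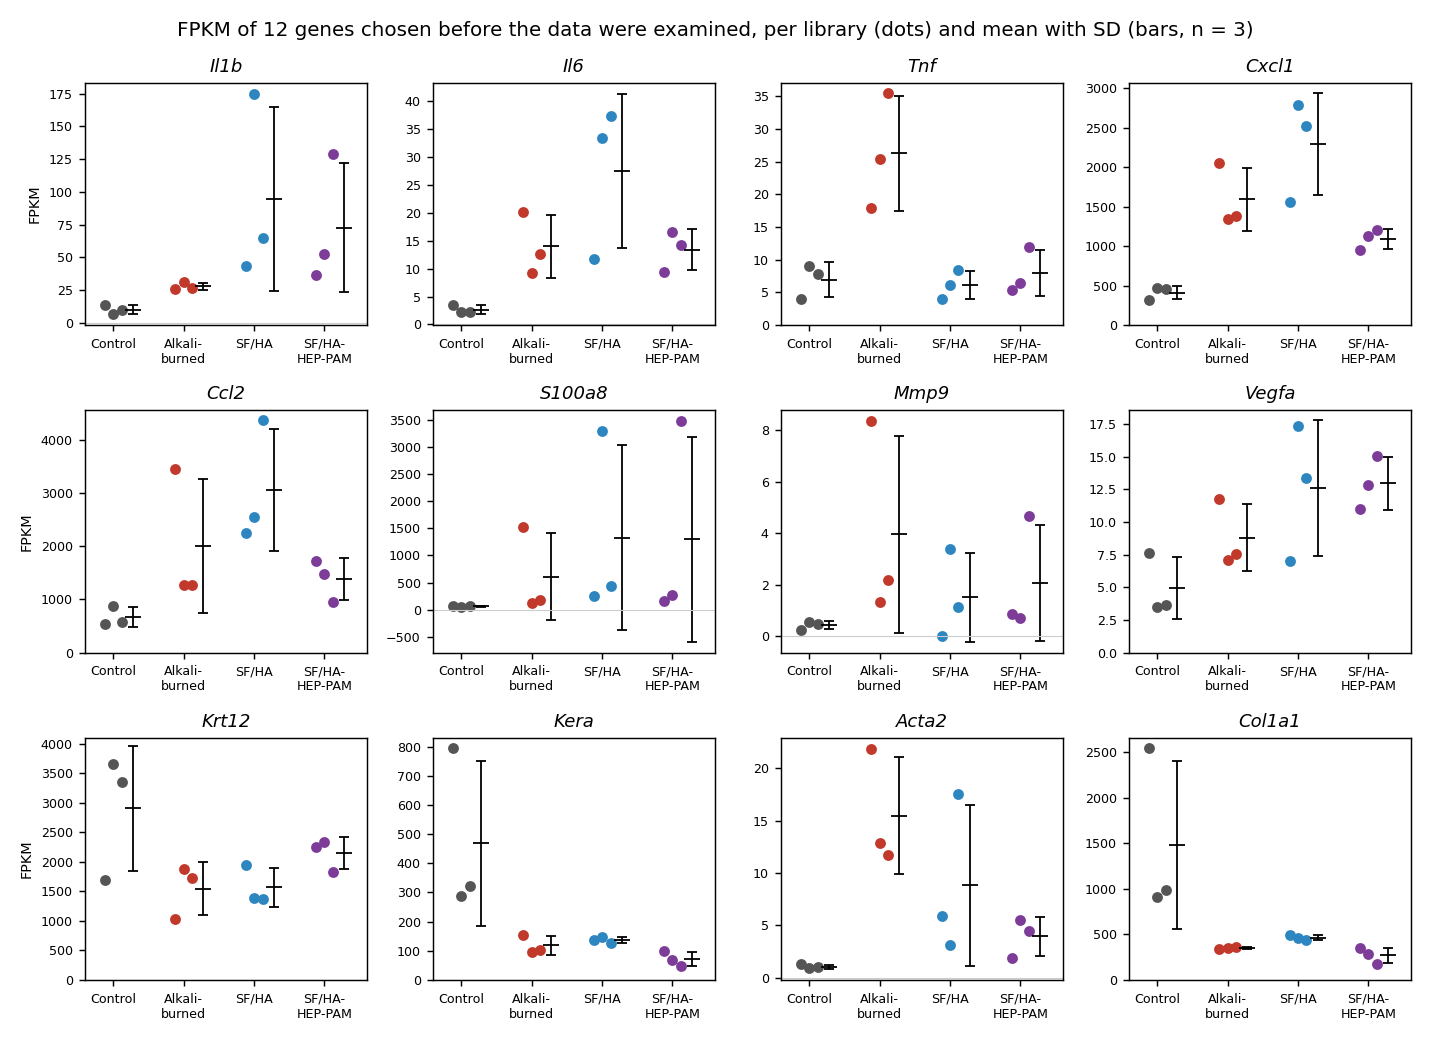
FPKM (vertical axes, linear) of the 12 genes chosen before the data were examined, per library (dots; replicates 1 to 3 from left) with mean and SD (bars, n = 3) in the 4 groups. Cxcl1 averages 412 FPKM in Control and 1593 in Alkali-burned corneas; S100a8 has 1 library far above the others in each group except Control.

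SF/HA against Alkali-burned compares the patch without HEP-PAM in its label with the injured group. Slc39a4, a zinc importer (ENSRNOG00000014314, chromosome 7, 108333381 to 108337553), fell from 154 ± 27.5 to 30.6 ± 5.36 FPKM (SD, n = 3; log2 -2.29, SE 0.21, adjusted p = 0.00059). The serine protease Prss30 (-2.65), the membrane mucin Muc20 (-2.52), the ion transport regulator Fxyd4 (-2.43), the tetraspanin Tspan1 (-2.33) and S100a7a (-2.11) fell as well. Adm rose from 21.9 ± 2.75 to 113 ± 26.2 FPKM (log2 2.29, SE 0.29, adjusted p = 0.00324), as did Odc1 of polyamine synthesis (1.43) and the protease-activated receptor F2rl1 (1.41).

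Of 17 interferon genes 4 fell under SF/HA and 13 were not called (6 fell adjusted over the list alone; median -0.92, camera adjusted p = 1.5e-08, adjusted p = 0.285 with an estimated correlation). They included Cmpk2 (-1.83), the transcription factor Irf1 (-1.39) and Oasl (-1.20). Of 7 MHC class II genes 2 rose (3 adjusted over the list alone; adjusted p = 7.41e-06, and 0.252 with an estimated correlation), RT1-Da among them (1.25), and of 20 chemokines 1 rose, Ccl20 (1.76; 1 adjusted over the list alone; adjusted p = 4.74e-05, and 0.252 with an estimated correlation). The chemokine Ccl3 was not called (1.92, SE 0.64, adjusted p = 0.161). Of 13 mitochondrially encoded genes 1 rose, Mt-nd3 (1.15; 2 adjusted over the list alone; adjusted p = 7.41e-06, and 0.296 with an estimated correlation). Epithelium markers (1 of 21 fell, 1 adjusted over the list alone; median 0.32, adjusted p = 0.00162), matrix proteases and inhibitors (0 of 15 called by limma, 1 adjusted over the list alone; adjusted p = 0.0235) and ribosomal proteins (0 of 38, also 0 adjusted over the list alone; adjusted p = 0.000313) also passed camera upward. With an estimated correlation these 3 gave adjusted p = 0.583, 0.583 and 0.632. Macrophage markers did not pass as a list (camera adjusted p = 0.0838): of 16, Tyrobp rose (1.60) while Cd68 (-1.34) and Arg1, an arginase (-1.87), fell. Tnf fell by 1.92 (SE 0.38, adjusted p = 0.0207). The transcription factor Cebpb (1.39) and the lipolysis inhibitor G0s2 (2.90) rose; without SF/HA replicate 2 G0s2 was 2.25 and not called (adjusted p = 0.0864).

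In all, 23 genes were higher and 126 lower under SF/HA than after the burn, 15.4% higher. The count of 149 became 74 without Alkali-burned replicate 2, 75 without Alkali-burned replicate 3 and 75 without SF/HA replicate 2, and the 7 called lists became 11 without SF/HA replicate 1. Of 21 called genes named, 15 kept the call in every such fit, while Tnf, Cebpb, G0s2, Ccl20, Tyrobp and RT1-Da lost it. All 6 lost it without Alkali-burned replicates 2 or 3 or SF/HA replicate 2 (highest adjusted p = 0.154, 0.156 and 0.138). Tyrobp and RT1-Da lost it without Alkali-burned replicate 1 (up to 0.0657), Tnf and Cebpb without SF/HA replicate 1 (up to 0.0751), and Ccl20 and RT1-Da without SF/HA replicate 3 (up to 0.0933). The other fixed genes were not called: Il1b 1.47 (adjusted p = 0.191), Il6 0.84 (0.351), Cxcl1 0.51 (0.345), Ccl2 0.72 (0.422), S100a8 1.14 (0.735), Mmp9 -0.96 (0.512), Vegfa 0.42 (0.606), Krt12 0.05 (0.967), Kera 0.24 (0.816), Acta2 -0.98 (0.353) and Col1a1 0.41 (0.639).

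SF/HA-HEP-PAM against Alkali-burned asks the same of the patch with HEP-PAM in its label. Duoxa2, a maturation factor of a hydrogen peroxide-producing oxidase (ENSRNOG00000017805, chromosome 3, 109245476 to 109248968), fell from 117 ± 14.4 to 8.78 ± 2.01 FPKM (SD, n = 3; log2 -3.61, SE 0.26, adjusted p = 2.48e-05). Slc39a4 fell from 154 ± 27.5 to 17.0 ± 3.74 FPKM (-3.11, SE 0.21, adjusted p = 1.68e-05), with Muc20 (-3.25), Prss30 (-3.21), Tspan1 (-3.19), Fxyd4 (-3.06), the crosslinking enzyme Tgm2 (from 70.7 to 7.97 FPKM), Mab21l4 (-2.94) and S100a7a (-1.86). Grhl3, a transcription factor of barrier epithelium, rose from 1.02 ± 0.170 to 11.8 ± 1.92 FPKM (2.66, SE 0.20, adjusted p = 4.11e-05). The connexin Gjb2 rose from 10.1 ± 3.58 to 131 ± 47.0 FPKM (3.57, SE 0.55, adjusted p = 0.00177), and so did the protease inhibitor Serpinb2 (3.81, and 4.42 without SF/HA-HEP-PAM replicate 1), Polg2 of mitochondrial DNA replication (3.39), Adm (2.91), the hormone Pthlh (2.83) and Etv3 (2.63).

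Of 21 corneal epithelium markers 10 rose and 1 fell (11 and 2 adjusted over the list alone; median 1.04, camera adjusted p = 0.000877, adjusted p = 0.725 with an estimated correlation), Gjb2 and the desmosome genes Dsc3 (1.75) and Pkp1 (1.63) among them. Of 19 myofibroblast and matrix genes 5 fell (5 adjusted over the list alone; median -0.78, adjusted p = 0.000713, and 0.725 with an estimated correlation), with Tagln (-2.02), Acta2 (-1.77, SE 0.50, adjusted p = 0.0299) and the proteoglycan Bgn (-1.23). Of 11 keratocyte markers 4 fell (4 adjusted over the list alone; adjusted p = 0.00303, and 0.725 with an estimated correlation), Fmod (-1.24) among them. Of 17 interferon genes 4 fell (4 adjusted over the list alone; adjusted p = 0.00130, and 0.725 with an estimated correlation), with Cmpk2 (-2.28) and Irf1 (-1.23). Of 9 complement genes 1 fell (1 adjusted over the list alone; adjusted p = 0.0371, and 0.725 with an estimated correlation). In lists that did not pass, single genes were called. Immediate early genes (adjusted p = 0.0776) had 3 of 16 higher: Klf6 (1.79), Klf4 (1.65) and Fosl1 (1.45). Matrix proteases and inhibitors (0.830) had 4 of 15 higher, with Mmp13 (2.51), the urokinase Plau (1.42) and its receptor Plaur (1.45). The unfolded protein and heat shock response (0.830) had 3 of 17 higher and 1 lower, with Sesn2 (1.77) and Dnajb1 (1.48). Hypoxia and glycolysis (0.134) had 3 of 13 higher: Adm, Ndrg1 (1.47) and the glucose transporter Slc2a1 (1.33). After the burn Ndrg1 (1.07 to 2.04 FPKM), Slc2a1 (1.43 to 2.24), Mmp13 (0.799 to 1.66), Dsc3 (1.73 to 2.91) and Pkp1 (1.39 to 2.71) lay near the pseudocount of 1. The size of their rises depends on this pseudocount. Macrophage markers (0.127) had 3 of 16 lower, Arg1 (-2.05), Spp1 (-1.69) and Cd68 (-1.65), and 1 higher. In stressed and cornifying epithelium (0.917), with 1 of 11 higher and 3 lower, the stress keratin Krt17 rose by 2.26. Tnf fell by 1.63 (SE 0.38, adjusted p = 0.0126).

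In all, 451 genes were higher and 227 lower, 66.5% higher; the share was 50.2% after median-of-ratios scaling and 55.1% after quantile normalization. Of the 451 higher genes 126 were not protein-coding, and among genes ordered by length the median log2 difference on recovered reads ran from -0.19 in the shortest 10% to 0.40 in the longest 10%. Of 39 called genes named, 33 kept the call whichever library was left out. Bgn lost it in all 6 fits (adjusted p up to 0.115), Acta2 without any burned library or SF/HA-HEP-PAM replicates 1 or 3 (up to 0.104), and Spp1 without any but Alkali-burned replicate 2 (up to 0.104). Fmod lost it without Alkali-burned replicate 1 or SF/HA-HEP-PAM replicate 3 (up to 0.0758), Tnf without Alkali-burned replicate 3 or SF/HA-HEP-PAM replicate 1 (up to 0.0530), and Tagln without SF/HA-HEP-PAM replicate 1 (0.0520). The other fixed genes were not called: Il1b 1.14 (adjusted p = 0.152), Il6 -0.03 (0.974), Cxcl1 -0.52 (0.169), Ccl2 -0.41 (0.522), S100a8 0.69 (0.751), Mmp9 -0.66 (0.511), Vegfa 0.53 (0.300), Krt12 0.51 (0.270), Kera -0.74 (0.189) and Col1a1 -0.44 (0.420). Of these Il1b passed with voom, a fit added after the data were seen (adjusted p = 0.0492).

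**Figure D3:**
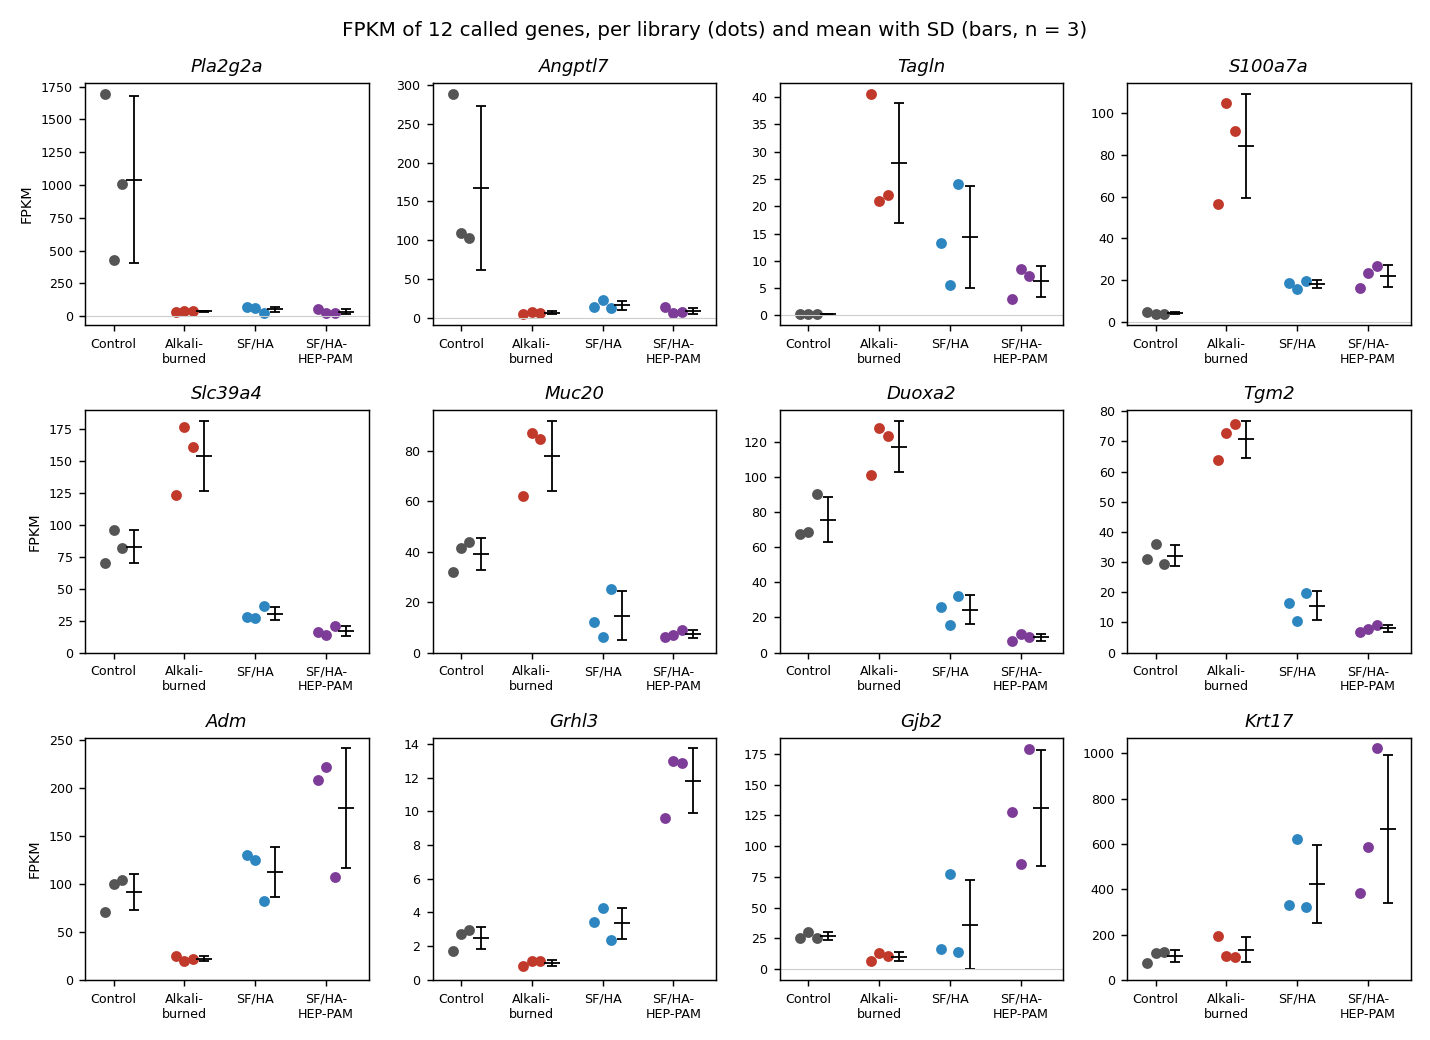
FPKM (vertical axes, linear) of 12 called genes per library (dots; replicates 1 to 3 from left) with mean and SD (bars, n = 3) in the 4 groups. Slc39a4 averages 154 FPKM after the burn, 30.6 under SF/HA and 17.0 under SF/HA-HEP-PAM; Adm averages 21.9, 113 and 179 FPKM.

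Both patch groups changed many of the same genes against the burn. Of 6112 genes 98 were lower in both and 15 higher in both, where independent lists of these sizes would share 4.68 and 1.70, and 0 were called in opposite directions by limma. The lower genes included Slc39a4, Muc20, Prss30, Tspan1, Fxyd4, Duoxa2, Tgm2, Cd68, Arg1, Irf1 and Cmpk2, and the higher ones Adm, Grhl3, Odc1, F2rl1, Cebpb and G0s2. Both comparisons use the 3 burned libraries, which alone makes their results alike. In 100 simulations that left both patches at the burned level and shuffled the libraries' residuals, 0 genes were shared in either direction. In a second form, which drew residuals with replacement so that 1 library could fill several places of a group, the median was 0 and the highest 155 lower and 61 higher. Of the 98 genes lower in both, 45 had been called higher after the burn, 0 lower, and 53 were not called there. Against Control the 98 genes had a median of -0.63 under SF/HA, with 19 called lower and 2 higher. Under SF/HA-HEP-PAM it was -0.82, with 35 lower and 2 higher. As the genes were picked for low patch values, these medians are lowered by the choice itself.

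Genes higher after the burn had a lower median under SF/HA-HEP-PAM than in any simulated patch without effect. The ranges were simulated only with all 12 libraries and a pseudocount of 1. Fits on fewer libraries or at another pseudocount have no range of their own, so their place against these ranges decides nothing. Under SF/HA the median of genes higher after the burn was below the simulated ranges with all libraries, but at -0.42 without Control replicate 1 it lay within them. It also lay within the wider range, from drawing with replacement, without Control replicate 3 (-0.51), Alkali-burned replicates 2 or 3 (-0.52 in both fits) or SF/HA replicates 1 or 2 (-0.56 and -0.49). For genes lower after the burn both medians lay within the ranges with all libraries, but without Alkali-burned replicates 2 or 3 that of SF/HA-HEP-PAM lay above both (1.25 and 0.81), as it did at a pseudocount of 0.1 (0.92). Above the range from shuffled residuals alone lay SF/HA-HEP-PAM without Control replicate 1 (0.67) or SF/HA-HEP-PAM replicate 3 (0.70) and SF/HA without Alkali-burned replicate 2 (0.57). The 270 genes higher after the burn had a median log2 difference from Alkali-burned of -0.58 under SF/HA (SD 0.27 between libraries, n = 3) and -0.71 under SF/HA-HEP-PAM (SD 0.05). The 78 lower ones had medians of 0.40 (SD 0.13) and 0.53 (SD 0.37). The value of 0.53 became 0.12 without Control replicate 2, and that of 0.40 became 0.25 without SF/HA replicate 1. Simulated patches without effect gave -0.13 (range -0.48 to 0.12) and -0.12 (-0.38 to 0.12) for the higher genes and 0.14 (-0.23 to 0.55) and 0.16 (-0.30 to 0.62) for the lower ones, since genes picked for a high burned value tend to be lower in any other group. With residuals drawn with replacement the ranges were -0.56 to 0.14 and -0.65 to 0.13 for the higher and -0.22 to 0.61 and -0.18 to 0.76 for the lower genes. Of the genes higher after the burn 55 were called lower under SF/HA and 82 under SF/HA-HEP-PAM; the simulated medians were 0 and the highest counts 9 and 2, or 123 and 178 when residuals were drawn with replacement. Across genes the covariance of the patch's difference from the burn with the burn's difference from Control was -0.194 for SF/HA and -0.220 for SF/HA-HEP-PAM. Shuffled residuals gave -0.236 to 0.0492 and -0.193 to 0.0255, and drawing with replacement -0.356 to 0.0914 and -0.384 to 0.0560. Only SF/HA-HEP-PAM lay below a range, that from shuffling. The correlations of -0.464 and -0.375 lay within the ranges of both forms. A contrast sharing no library, the difference between both patches against the difference between burn and Control, had a correlation across genes of -0.05 (jackknife SE 0.08). Genes are not independent replicates.

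SF/HA-HEP-PAM against SF/HA tests the difference between both patches itself. Polg2 was 27.6 ± 9.34 FPKM under SF/HA-HEP-PAM and 1.06 ± 0.844 under SF/HA (SD, n = 3; log2 3.82, SE 0.33, adjusted p = 0.000219; ENSRNOG00000013728, chromosome 10, 91712586 to 91723008). The transcription factor Etv3 rose by 2.58 (SE 0.34, adjusted p = 0.00255), the Notch ligand Jag1 by 2.20 (SE 0.30, adjusted p = 0.00289), Hlf by 2.09 (SE 0.32, adjusted p = 0.00461) and Sesn2 by 1.26 (SE 0.17, adjusted p = 0.00289). Gjb2 (2.19, and 2.95 without SF/HA replicate 2), Sox9 (1.98) and Klf4 (1.09) were also higher. Under SF/HA Polg2 (0.401 to 2.01 FPKM), Hlf (1.04 to 2.02), Jag1 (1.39 to 4.47) and Etv3 (1.77 to 5.99) lay near the pseudocount of 1. The size of their differences depends on this pseudocount. Lower were Lgals1 (-1.49), Apod (-1.40), S100a4 (-1.39), Igfbp4 (-1.29), and the proteoglycans Dcn (-1.21) and Lum (-1.11), with Cox6a2 (-1.73), Duoxa2 (-1.34), Mt1 (-1.09), Timp1 (-1.07) and Cxcl1 (-1.03, SE 0.25, adjusted p = 0.0340).

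Of 22 lists 10 passed camera downward and 1 upward, and 0 passed with an estimated correlation or in fry. Keratocyte markers had 2 of 11 lower (3 adjusted over the list alone; median -0.80, adjusted p = 4.7e-06, and 0.309 with an estimated correlation). Of 19 myofibroblast and matrix genes 0 were called by limma (also 0 adjusted over the list alone; median -0.78, camera adjusted p = 2.98e-07, adjusted p = 0.322 with an estimated correlation). Macrophage markers (0 of 16 called, median -0.53, adjusted p = 5.65e-06), MHC class II (0 of 7, -0.55, 0.000686), complement (0 of 9, -0.67, 0.000571) and mitochondrially encoded genes (0 of 13, -0.51, 5.65e-06) also passed downward; adjusted over the list alone 1 complement gene fell and 0 of the others were called. Chemokines (1 of 20 lower, -0.62, 0.000569) and oxidative stress genes (1 of 14 lower, 2 adjusted over the list alone, -0.27, 0.000569) followed, with Cxcl1 and Mt1; these 6 lists gave adjusted p = 0.234 with an estimated correlation. Ribosomal proteins (median -0.22, adjusted p = 2.89e-08) and angiogenic factors (-0.43, 0.0496) had 0 called genes and gave adjusted p = 0.413 and 0.564 with an estimated correlation. Epithelium markers passed upward, with 2 of 21 higher (3 adjusted over the list alone; adjusted p = 0.00683, and 0.609 with an estimated correlation).

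In all, 235 genes were higher and 32 lower, 88.0% higher, against 64.7% after median-of-ratios scaling and 70.8% after quantile normalization; the median of all genes was itself 0.13. Of the 235 higher genes 91 were not protein-coding, and the longest 10% of genes had a median of 0.40 against -0.11 in the shortest. The count of 267 became 150 without SF/HA replicate 3 and 88, 162 and 89 without SF/HA-HEP-PAM replicates 1, 2 and 3. Of 19 called genes named, Polg2, Etv3, Jag1, Hlf and Sesn2 kept the call whichever library was left out. The others lost it in at least 1 fit: 8, 6 and 13 genes without SF/HA replicates 1, 2 and 3 (highest adjusted p = 0.102, 0.0969 and 0.165) and 13, 9 and 13 without SF/HA-HEP-PAM replicates 1, 2 and 3 (0.154, 0.0867 and 0.164). The other fixed genes were not called: Il1b -0.33 (adjusted p = 0.741), Il6 -0.86 (0.234), Tnf 0.29 (0.666), Ccl2 -1.13 (0.116), S100a8 -0.45 (0.864), Mmp9 0.30 (0.809), Vegfa 0.11 (0.873), Krt12 0.46 (0.389), Kera -0.98 (0.133), Acta2 -0.79 (0.355) and Col1a1 -0.85 (0.169). Of these Il6 passed without SF/HA replicate 1 (-1.37, adjusted p = 0.0476) and Ccl2 with voom, added after the data were seen (0.0413).

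SF/HA against Control sets that patch group beside the Control corneas. The protease inhibitor Timp1 rose from 12.6 ± 2.08 to 188 ± 54.9 FPKM (SD, n = 3; log2 3.76, SE 0.29, adjusted p = 0.000101), with G0s2 (4.20, and 3.54 without SF/HA replicate 2), Cfd (3.65, and 3.04 without Control replicate 2), the chitinase-like Chi3l1 (3.56), Mmp3 (3.37, SE 0.21, adjusted p = 4.2e-05) and the metallothionein Mt2A (2.86). Pla2g2a (-4.18), Chad (-3.56), Angptl7 (-3.20), Npy (-3.19) and the secreted epithelial Slurp1 (-2.75) fell. Macrophage markers rose in 11 of 16 cases and fell in 1 (11 and 1 adjusted over the list alone; median 1.83, camera adjusted p = 5.27e-12, adjusted p = 0.0462 with an estimated correlation), the only list in any comparison that passed both ways on FPKM; C1qc (3.47), Lyz2 (3.39), Tyrobp (3.38) and C1qa (3.17) led it. In Control C1qc (0.313 to 1.91 FPKM), Tyrobp (1.76 to 4.27) and C1qa (1.70 to 4.26) lay near the pseudocount of 1, so the size of their rises depends on it. On recovered reads, in the fit added after the data were seen, 5 lists passed both ways in this comparison: chemokines, macrophage markers, NF-kB and innate signalling and complement (adjusted p = 0.0325 with an estimated correlation) and MHC class II (0.0368). Of 20 chemokines 9 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 2.12e-08, and 0.0617 with an estimated correlation), with Ccl3 (3.48, and 2.82 without SF/HA replicate 2), Ccl20 (3.13), Ccl7 (2.99), Cxcl1 (2.45, SE 0.25, adjusted p = 0.000583) and Ccl2 (2.17, SE 0.41, adjusted p = 0.0124) up and Cxcl14 (-1.57) down. Of 7 MHC class II genes 5 rose (5 adjusted over the list alone; adjusted p = 6.58e-08, and 0.0711 with an estimated correlation), with Cd74 (2.63) and RT1-Da (2.15). Of 16 cytokines 6 rose (7 adjusted over the list alone; adjusted p = 2.02e-05, and 0.0840 with an estimated correlation), with Il1b (2.90, SE 0.53, adjusted p = 0.0105), Il6 (2.83, SE 0.42, adjusted p = 0.00372) and the growth factor Csf3 (2.71). Of 9 complement genes 6 rose (6 adjusted over the list alone; adjusted p = 2.42e-07, and 0.0717 with an estimated correlation), Serping1 among them (3.11), and of 15 matrix proteases and inhibitors 6 rose (6 rose and 1 fell adjusted over the list alone; adjusted p = 1.85e-06, and 0.137 with an estimated correlation), Plau among them (1.95). Vcam1 (2.21), Sod2 (2.45) and Clu (2.74) rose. Corneal epithelium markers passed downward, with 4 of 21 lower and 2 higher (the same counts adjusted over the list alone; median -0.29, adjusted p = 0.0172, and 0.476 with an estimated correlation); Krt15 rose (2.17). The Krt15 entry spans 104998 bases and overlaps Krt9, with 0 reads, on the same strand. Whether all its reads are of Krt15 was not tested. The other 8 of 15 called lists, 7 up and 1 down, gave adjusted p between 0.081 and 0.476 with an estimated correlation.

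In all, 195 genes were higher and 84 lower than in Control, and 31 of 35 called genes named kept the call whichever library was left out. Acta2 (1.99, SE 0.50, adjusted p = 0.0428) lost it in every fit but that without SF/HA replicate 2 (adjusted p up to 0.119), and was 1.38 without SF/HA replicate 3. Kera (-1.61, SE 0.38, 0.0311) and Col1a1 (-1.504, SE 0.36, 0.0339) lost it without any 1 of the SF/HA libraries (up to 0.0885 and 0.0936), and Krt15 without Control replicate 2 or SF/HA replicate 2 (up to 0.0684). Tnf was -0.13 (SE 0.38, adjusted p = 0.889), S100a8 3.58 (SE 1.32, 0.143) and Mmp9 0.57 (SE 0.65, 0.662). Krt12 was -0.83 (SE 0.31, 0.148) and passed without Control replicate 1 (-1.18, 0.0229). Vegfa was 1.19 (SE 0.34, 0.0695) and passed without Control replicate 1 or SF/HA replicate 1 (0.0232 and 0.0247). Both passed with library weights (adjusted p = 0.0262 for Krt12 and 0.0181 for Vegfa), and Vegfa at 5 FPKM or more (0.0472). Of the added settings, S100a8, Krt12 and Vegfa passed without the 4 libraries that stood apart (0.0105, 0.0145 and 0.0348), and Vegfa with voom (0.0182) and at least 10 reads (0.0419). For S100a8 and Krt12 the pass without the 4 libraries is no support, since these stood apart in those genes.

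In SF/HA-HEP-PAM against Control 563 genes were higher and 146 lower. Sox9, a transcription factor of progenitor cells, rose from 5.74 ± 2.46 to 57.7 ± 21.5 FPKM (SD, n = 3; log2 3.13, SE 0.42, adjusted p = 0.000986), with Ly6d (3.85), S100a9 (3.81, SE 0.99, adjusted p = 0.0206), Polg2 (3.75) and Lyz2 (3.004). S100a9 was 4.43 without SF/HA-HEP-PAM replicate 1, and 2.85 and not called without SF/HA-HEP-PAM replicate 3 (adjusted p = 0.0759). Pla2g2a (-4.76), Angptl7 (-4.00), Chad (-3.67), Npy (-3.08), Duoxa2 (-2.98), Slurp1 (-2.95), the microfibril gene Mfap4 (-2.93) and the protease inhibitor Csta (-2.85) fell. Of 20 chemokines 9 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00750, and 0.326 with an estimated correlation), with Cxcl3 (2.79), Ccl20 (2.03) and Cxcl1 (1.42, SE 0.25, adjusted p = 0.00372). Of 16 cytokines 8 rose (9 adjusted over the list alone; adjusted p = 0.00576, and 0.326 with an estimated correlation), with Il1b (2.58, SE 0.53, adjusted p = 0.00765) and Il6 (1.97, SE 0.42, adjusted p = 0.00900). Of 16 macrophage markers 9 rose and 1, Arg1 (-2.14), fell (9 and 1 adjusted over the list alone; adjusted p = 0.00160, and 0.326 with an estimated correlation); Tyrobp rose by 2.51. Of 7 MHC class II genes 5 rose (5 adjusted over the list alone; adjusted p = 0.00914, and 0.326 with an estimated correlation), Cd74 among them (1.96), and of 16 NF-kB and innate signalling genes 6 rose (6 adjusted over the list alone; adjusted p = 0.00127, and 0.326 with an estimated correlation), Icam1 among them (2.12). Of 15 matrix proteases and inhibitors 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.00256, and 0.326 with an estimated correlation), with Timp1 (2.69), Plau (2.57), Mmp3 (2.49) and Plaur (2.28). Stressed and cornifying epithelium had 6 of 11 higher (6 adjusted over the list alone; adjusted p = 0.0178, and 0.357 with an estimated correlation), Krt17 among them (2.56), and cell cycle genes 3 of 14, with Mcm4 (1.39) and Rrm2 (1.48; 3 adjusted over the list alone; adjusted p = 0.00256, and 0.391 with an estimated correlation). Klf6 (1.51), Fosl1 (adjusted p = 0.00159), Sesn2 (2.17), the glycolytic Pkm (1.41) and Krt15 (2.35) rose. Keratocyte markers had 3 of 11 lower (3 adjusted over the list alone; adjusted p = 0.00145, and 0.368 with an estimated correlation), Kera among them (-2.59, SE 0.38, adjusted p = 0.00147). Myofibroblast and matrix genes had 6 of 19 lower and 1 higher (7 and 1 adjusted over the list alone; median -0.10, adjusted p = 0.00256, and 0.482 with an estimated correlation), with Col1a1 (-2.35, SE 0.36, adjusted p = 0.00184), Col1a2 (-2.15) and Sparc (-1.82). The other 4 of 14 called lists, 3 up and 1 down, gave adjusted p = 0.326 with an estimated correlation.

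The share of higher genes was 79.4%, against 66.7% after median-of-ratios scaling and 57.6% after quantile normalization, and the median of all genes was 0.14. Of the higher genes 139 were not protein-coding, and the longest 10% of genes had a median of 0.34 against 0.08 in the shortest. Of 39 called genes named, 37 kept the call whichever library was left out. Vegfa (1.30, SE 0.34, adjusted p = 0.0222) lost it without Control replicates 2 or 3 (0.0752 and 0.0738) or SF/HA-HEP-PAM replicates 2 or 3 (0.0598 and 0.0814), and S100a9 without Control replicates 2 or 3 or SF/HA-HEP-PAM replicate 3 (up to 0.0759). Not called were Tnf 0.16 (SE 0.38, adjusted p = 0.801), Ccl2 1.04 (SE 0.41, 0.103), S100a8 3.13 (SE 1.32, 0.1197), Mmp9 0.88 (SE 0.65, 0.378), Krt12 -0.37 (SE 0.31, 0.439) and Acta2 1.20 (SE 0.50, 0.115). Of these Acta2 passed with library weights (adjusted p = 0.0345) and with only the compared libraries (0.0436), and, in settings added after the data were seen, Ccl2 with voom (0.0394) and S100a8 without the 4 libraries that stood apart (0.0182). That pass of S100a8 is no support for a rise, since SF/HA-HEP-PAM replicate 3 stood apart in S100a8 itself.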

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

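Fixed before the data were examined were the direct comparison of both patches with its lists and left-out fits and the splits and regroupings of libraries. The tests of neutrophil markers and of a few genes taking most of the reads were written before their results were seen. They concern a pattern found in these data, so they were not fixed before the data were examined. The other tests in this part were chosen only after the result was seen.

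The effects of both patches against the same burned group differed in a direct test, SF/HA-HEP-PAM against SF/HA, with 267 genes and 11 lists called. Of these lists 0 passed with an estimated correlation (lowest adjusted p = 0.234) and 0 in fry, and 3 of 10 splits of the libraries gave as many (highest other 14). Among named genes Polg2 (3.82), Etv3 (2.58), Jag1 (2.20), Gjb2 (2.19), Hlf (2.09), Sox9 (1.98), Sesn2 (1.26) and Klf4 (1.09) were higher with HEP-PAM in the label. Cox6a2 (-1.73), Lgals1 (-1.49), Apod (-1.40), S100a4 (-1.39), Duoxa2 (-1.34), Igfbp4 (-1.29), Dcn (-1.21), Lum (-1.11), Mt1 (-1.09), Timp1 (-1.07) and Cxcl1 (-1.03) were lower. Leaving out SF/HA-HEP-PAM replicate 1 or 3 brought the count to 88 or 89. On recovered reads the median log2 difference of all genes ran from -0.11 in the shortest 10% to 0.40 in the longest. Of the genes named higher, all but Sox9 and Klf4 are longer than the median gene tested on FPKM (8470.5 bases). Only Jag1 and Hlf are longer than the median gene tested on recovered reads (21905 bases). Of those named lower, all but Apod, Igfbp4 and Dcn are shorter than 8470.5 bases, and all but Dcn shorter than 21905. How much of these differences follows gene length was not tested.

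Other groupings of all 12 libraries argued against chance for the F-test: 1 of 100, the real one, gave 1629 genes, and the highest other gave 471. With 100 groupings a share below 1 in 100 cannot be shown. The test also cannot tell the group labels from anything else shared by the libraries of a group. For 3 against 3 libraries there are 10 splits, too few for a share below 0.05. For called genes 1 of 10 was as large in every comparison: Alkali-burned against Control 348 (highest other 3), SF/HA against Alkali-burned 149 (3), SF/HA-HEP-PAM against Alkali-burned 678 (9), SF/HA-HEP-PAM against SF/HA 267 (4), SF/HA against Control 279 (4) and SF/HA-HEP-PAM against Control 709 (4). For lists the splits as large numbered, in the same order, 1 (13, highest other 9), 5 (7, highest other 17), 8 (5, highest other 10), 3 (11, highest other 14), 2 (15, highest other 15) and 1 (14, highest other 13).

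SF/HA-HEP-PAM libraries carried more reads on long and non-coding genes: 10547, 8257 and 9463 RPM (reads relative to library size) on lncRNA genes, against 9411 in Control replicate 1 and 5885 to 6558 in the others. After thinning to equal depth the median log2 difference of 186 lncRNA genes was 0.72 (SD 0.19). These genes were picked before thinning, by at least 10 reads in 3 libraries. SF/HA-HEP-PAM libraries, the deepest on average, can meet that alone, so the difference does not decide about library depth. The RPM above cover all lncRNA genes and use no such filter. Genomic DNA is argued against: reads on 1306 silent receptor genes rose by 8.40 RPM (SE 10.9), where DNA in proportion to the lncRNA excess would add 715. More unspliced or nuclear RNA stays open, as small-RNA features had more RPM in all 27 pairs of an SF/HA-HEP-PAM with another library, while the share of mitochondrial protein-coding reads was lower in 13 of them. Mitochondrial rRNA, not part of that test, took 1.32% to 1.84% of reads in SF/HA-HEP-PAM libraries and 2.51% to 5.49% in the others. An effect of the patch on transcription is untested and shares its libraries with the explanation by unspliced or nuclear RNA.

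S100a8 and S100a9, calprotectin subunits abundant in neutrophils, took far more reads in 1 library of each group but Control: 6641 RPM in Alkali-burned replicate 1 (others 1280 and 1451), 17198 in SF/HA replicate 2 (1666 and 2768) and 19827 in SF/HA-HEP-PAM replicate 3 (2114 and 3183). Library depth is argued against, since the smallest excess over the next library after thinning was 4.52-fold. A few genes taking most of the reads is argued against by the shares in these libraries. The pair took 0.664%, 1.72% and 1.98% (interval of the last 1.96 to 2.01), and the most read gene 2.55%, 3.64% and 1.80%. The test as written before its result was seen stayed undecided: S100a9 was itself the most read gene of SF/HA-HEP-PAM replicate 3. It had 18022 RPM there against 2033 and 3045 in its group, and as a gene of the pattern it decides nothing. More neutrophils in those libraries may account for part of it and stay open: 14 other neutrophil markers with reads peaked in the same library in 2 of 3 groups, by 3.73-fold and 2.30-fold, but in Alkali-burned in replicate 2, by 1.04-fold. Most of those reads are of Lcn2, which epithelium also makes; without it the sums were 46.1 RPM against 28.4 in the next SF/HA library and 53.8 against 30.7 in the next SF/HA-HEP-PAM library, and a difference between animals in the response is untested.

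The 98 genes called lower under both patches than after the burn included Prss30, Muc20 and Slc39a4. A smaller share of epithelium in the patch libraries is argued against, since the epithelium list had medians of 0.32 under SF/HA and 1.04 under SF/HA-HEP-PAM. Conjunctival tissue in the burned libraries stays open. The 5 measured genes of that list had a median of -0.51 in Alkali-burned against Control, with 1 called lower and 4 not called (camera adjusted p = 0.244). This gave no sign of such tissue, but 5 of 16 listed genes are too few to decide it. Fewer surface-layer cells in the patch libraries may contribute and stay open: surface minus basal layer medians were -1.01 and -1.27 against Alkali-burned and -0.59 and -1.07 against Control for SF/HA and SF/HA-HEP-PAM. For SF/HA-HEP-PAM the gap came mainly from the basal set (medians 0.99 and 0.88; surface set -0.28, with 5 of 16 genes lower and 3 higher, and -0.20), for SF/HA against Alkali-burned from the surface set (-0.80, with 3 of 16 lower and 1 higher; basal set 0.22); an effect of the patches themselves is untested.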

How the results depend on the processing

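Voom, thinning, the read minimum, protein-coding genes only and the set without 4 libraries were chosen after seeing the data. Of 397 values of counts, lists and medians under other settings, 330 stayed within 1.5 times (counts) or 1 SD (medians), 67 moved and 0 changed sign by the rule used, which counts only values beyond their spread; the correlation and covariance sharing no library, within their jackknife SE of 0, did turn positive at a pseudocount of 0.1. Of 4017 planned single-gene values 3766 kept their side of the threshold, 237 lost and 14 gained a call; of 1185 added ones 1154, 18 and 13 did; 0 called genes turned direction in either, while some genes not called, such as Krt12 in SF/HA against Alkali-burned, changed sign. The cause of the moves was not tested, except that fewer samples, a stricter p or no fold minimum change counts by construction. Comparisons follow in the order Alkali-burned against Control, SF/HA and then SF/HA-HEP-PAM against Alkali-burned, SF/HA-HEP-PAM against SF/HA, SF/HA and then SF/HA-HEP-PAM against Control.

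Called genes (348, 149, 678, 267, 279 and 709) became 188, 89, 336, 143, 139 and 345 with a pseudocount of 5 and 659, 238, 1903, 809, 421 and 1537 with voom. Without a filter Alkali-burned against Control became 217, SF/HA against Alkali-burned 88 and SF/HA against Control 174. An adjusted p below 0.01 gave 148, 69, 123, 127 and 466 for all but SF/HA-HEP-PAM against Alkali-burned; no fold minimum gave 575, 1376, 541 and 1341 for all but SF/HA against Alkali-burned and against Control. SF/HA-HEP-PAM against SF/HA fell to 173 at 5 FPKM or more and 177 with protein-coding genes only, and SF/HA against Control to 172 with only its own libraries. Leaving out 1 library gave 225 to 420, 74 to 183, 478 to 589, 88 to 319, 196 to 364 and 520 to 706; leaving out the 4 that stood apart gave 415, 182, 577, 236, 385 and 616.

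Called lists (13, 7, 5, 11, 15 and 14) became 0, 0, 0, 0, 1 and 0 with an estimated correlation. Fry gave 4 for SF/HA against Alkali-burned and 0 for SF/HA-HEP-PAM against SF/HA; no filter gave 14 for SF/HA and 9 for SF/HA-HEP-PAM against Alkali-burned, the latter with 3 at 5 FPKM or more. Leaving out 1 library gave 12 to 14, 6 to 11, 5 to 7, 9 to 14, 13 to 16 and 14 to 16. The F-test's 1629 genes became 1062 at 5 FPKM or more, 2729 with library weights, 2645 with voom, and 984 to 2027 leaving out 1 library.

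Medians of burn-called genes moved as follows. For SF/HA, higher genes (-0.58) ranged from -0.74 to -0.42 leaving out 1 library, and lower ones (0.40) from 0.25 to 0.57, with 0.27 at a pseudocount of 5. For SF/HA-HEP-PAM, higher genes (-0.71) had -0.77 at a pseudocount of 5, -0.78 at 5 FPKM or more, -0.86 with median-of-ratios scaling, -0.85 with quantile normalization and -0.85 to -0.69 leaving out 1 library. Its lower genes (0.53) had 0.92 at a pseudocount of 0.1 and 0.12 to 1.25 leaving out 1 library. The correlation sharing no library (-0.05) ranged from -0.09 to -0.01 leaving out 1 library, with 0.02 at a pseudocount of 0.1, and the covariance (-0.026) from -0.044 to -0.0064, with 0.029 at a pseudocount of 0.1.

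A replicate block gave 312, 151, 668, 245, 256 and 702 called genes. Of 237 values of named genes 231 kept their side of the threshold and 6 passed no longer: Ccl20 in SF/HA against Alkali-burned (adjusted p = 0.0783), Acta2 in SF/HA against Control (0.0688), and Cxcl1 (0.0520), Gjb2 (0.0513), Lum (0.0513) and Timp1 (0.0864) in SF/HA-HEP-PAM against SF/HA. Libraries with the same number correlated between -0.09 and 0.15 (18 pairs, 2 above 0.1; 6 of 12 libraries were closest to their own number). This shows no clear pairing by number, but with 3 libraries per group it cannot exclude one. Depth limits low genes: 40, 17, 96, 69, 29 and 115 called genes had fewer than 10 reads in 3 libraries.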

Other observations

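The tests on recovered reads in this part were chosen only after the data were seen. In that fit 3 further lists had enough genes. Corneal endothelium markers passed upward after the burn, with 4 of 9 genes higher (median log2 0.96, camera adjusted p = 0.00024, adjusted p = 0.151 with an estimated correlation). They passed downward under SF/HA against the burn, with 0 of 9 called by limma (-0.78, adjusted p = 0.00188, and 0.252 with an estimated correlation), and under SF/HA-HEP-PAM, with 5 of 9 lower and 1 higher (-1.28, adjusted p = 0.0262, and 0.618 with an estimated correlation). Vascular and lymphatic endothelium markers passed downward under SF/HA-HEP-PAM, with 2 of 5 lower against the burn (-0.78, adjusted p = 0.0114, and 0.618 with an estimated correlation) and 2 of 5 lower against SF/HA (-0.87, adjusted p = 0.00117, and 0.203 with an estimated correlation). Inflammasome and pyroptosis genes passed in no comparison (adjusted p from 0.274 to 0.975). Neutrophil, lymphocyte, Schwann cell and melanocyte, lens, skeletal muscle, retina and iris, erythrocyte and sex-linked markers had fewer than 5 measured genes in both fits and were not tested.

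Some lists that did not pass had a median, mean and camera direction of different sign. In SF/HA against Alkali-burned, myofibroblast and matrix genes (median -0.15, mean -0.11) and the unfolded protein and heat shock response (-0.11, -0.10) had an upward direction. In SF/HA-HEP-PAM against Alkali-burned mitochondrially encoded genes had 0.06, -0.01 and down, and in SF/HA-HEP-PAM against SF/HA matrix proteases and inhibitors had -0.07, 0.01 and down. In SF/HA against Control keratocyte markers had 0.18, -0.22 and up. In SF/HA-HEP-PAM against Control angiogenic factors (0.17, 0.02), interferon genes (0.05, 0.19) and oxidative stress genes (-0.02, 0.26) had a downward direction.

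Calls shared with the fit on recovered reads were 222 higher and 68 lower in Alkali-burned against Control, 20 and 102 in SF/HA and 373 and 208 in SF/HA-HEP-PAM against Alkali-burned, 165 and 27 in SF/HA-HEP-PAM against SF/HA, and 164 and 64 in SF/HA and 451 and 129 in SF/HA-HEP-PAM against Control, with 0 in opposite directions. In SF/HA against Alkali-burned 26.1% of the calls on recovered reads were higher, against 15.4% on FPKM. Thinned to 486264 reads, SF/HA-HEP-PAM libraries had 12164 to 12829 genes with reads and the other libraries 11416 to 12138.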
